A study of Homo sapiens with 29 samples.

How the data were processed

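PolyA RNA of 29 COLO320DM xenograft tumors was sequenced on a NovaSeq S4. The labels name the NEBNext Ultra II Directional kit under RNA extraction and the TruSeq stranded mRNA kit for the libraries, which leaves the kit used unclear. The labels name Trimmomatic 0.39, STAR 2.7.7a, featureCounts of Subread 2.4.2, edgeR 4.0.2 and GRCh38, and state neither their settings nor the annotation. They name no mouse genome, so reads of the mouse host may be counted under human genes. The deposited values are a signal made by the authors: gene counts divided by an effective library size, that is, CPM after a between-library scaling. The single table held 13492 genes in 29 columns, all of which were assigned to a sample, and 10 symbols occur more than once. Some symbols had become dates, so genes were matched by Ensembl ID. Columns summed to between 0.92 and 1.26 M. In each library 100% of values were whole multiples of 1 read within 0.05 reads, which gave back depths of 26.8 to 61.6 M reads. Counting error was small against the spread between libraries except for genes with few reads, such as DKK4 with Helicon4.

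Libraries were grouped by compound and dose as labelled. The choice of tests, gene lists, named genes and most alternatives was made before the data were examined, with 1 test for counts and another for CPM; the scaled values took the test for CPM. Genes with at least 1 CPM in at least 5 libraries (13373) were tested as log2(CPM + 1) with limma 3.58.1 in R 4.3.3 (trend and robust empirical Bayes), with all 4 groups in 1 fit and no covariate. Tests were two-sided, p values were adjusted by Benjamini-Hochberg over all genes, and 0.05 was the threshold. The 6 comparisons were Helicon4 at 100 mpk, Helicon4 at 30 mpk and Helicon4neg each against vehicle, the 2 doses of Helicon4 against each other, and either dose of Helicon4 against Helicon4neg. Errors of fold changes are standard errors and errors of CPM are SD between libraries.

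Gene lists were tested with camera at a preset correlation of 0.01, which treats members as nearly independent, and with an estimated correlation beside it. The 21 lists were Wnt targets, intestinal stem cell markers, Wnt pathway components, ribosome biogenesis and other MYC targets, co-amplified genes, S-phase, G2/M, enterocyte, secretory and neuroendocrine markers, hypoxia and glycolysis, p53 targets, ATF4 and unfolded protein responses, cholesterol synthesis, interferon response, immediate early genes, fibroblast, endothelial and leukocyte markers, muscle, fat and skin markers, and mitochondrial transcripts. Some genes belong to more than 1 list, AXIN2, LGR5 and EPHB3 among them. Called members were counted with p adjusted over all genes and over the list alone.

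The genes named were drawn from 12 core Wnt genes whether changed or not, the 8 largest rises and falls among genes with adjusted p under 0.05 and mean CPM of at least 5, and up to 4 members per list with the smallest adjusted p. Which list members were printed was chosen after their values were seen. Of these genes, 7 results whose calls were lost or reversed under alternatives were at first left out of the text, 5 of them also out of the counts over alternatives, and were then put back. Clone-style and pseudogene-style symbols were left out of the largest changes, and the pattern for pseudogenes also left out MFAP4 and PCP4. Genes outside this rule are given as chosen after their values were seen. XIST and Y-linked genes were not named. Of the named identifiers 225 of 225 were found under the same symbol in GENCODE 29, which is not known to be the authors' annotation.

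Library measures were compared with exact permutation tests of the difference in means, two-sided, and correlations between library measures with random permutations. Responses against the shared vehicle libraries were set beside 100 simulations of unchanged groups and 20 random divisions of the vehicle libraries into 2 sets. Replicate numbers do not pair the libraries: over 35 pairs of libraries with the same number the correlation of residuals ran from -0.70 to 0.52, with 15 above 0.1, and 0 of 27 libraries correlated best with one of their own number. The alternatives chosen beforehand were a pseudocount of 0.1, no filter, at least 5 CPM, TMM factors on the values, limma without trend and robust fitting, a fit of only the 2 groups, the replicate number or the title code as a block, a covariate of host markers, library weights, a minimum of 1.5-fold and each library left out. Alternatives added after the data were seen were edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 on recovered reads, a covariate of the length slope, and a fit without the libraries that stood apart. The quasi-likelihood test called 4047, 1514, 673, 2092, 457 and 4758 genes for Helicon4 at 100 mpk, at 30 mpk and Helicon4neg against vehicle, Helicon4 against Helicon4neg at 30 mpk, 100 against 30 mpk, and 100 mpk against Helicon4neg.

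The fit was tested on simulated data with known changes: at the sizes of the 100 mpk and vehicle groups it recovered 33 of 50 genes changed 1.5-fold and 46 of 49 changed 2-fold, and 4 of 183 calls were false. DESeq2 made 19 false calls of 201. These rates may not carry over to the real libraries, which differ in title code and share a component with 41% of the variance. Python 3.11.15, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for library tests and figures.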

Results

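Gene expression was measured by RNA-seq of polyA RNA in 29 libraries from mouse xenografts of COLO320DM, a human colorectal adenocarcinoma cell line with amplified MYC. Tumors labelled 48 h had received vehicle (n = 10 libraries), Helicon4neg_30mpk (n = 8), Helicon4_30mpk (n = 6) or Helicon4_100mpk (n = 5), where mpk is the dose unit as labelled. The series describes Helicon4 as a helicon peptide aimed at the binding of β-catenin to TCF transcription factors, and the labels give no structure for either compound. Replicate numbers are the only sign in the labels that libraries within a group came from separate animals. Whole reads recovered from the values, in units of M (mega), numbered 26.8 to 60.9 M per library for vehicle and 27 to 59.4 M for Helicon4neg. They numbered 40.8 to 48.6 M for Helicon4 at 30 mpk and 34.3 to 61.6 M at 100 mpk. Values below are CPM on the authors' scaling, and fold changes are differences of mean log2(CPM + 1), which understate changes of genes near 1 CPM.

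Library titles carried codes whose meaning is not stated. Code SH7080 held 2 vehicle and 5 Helicon4neg libraries, code SH7081 held 3 Helicon4neg libraries and 1 of Helicon4 at 30 mpk, and code SH7083 held 1 of Helicon4 at 30 mpk and 4 at 100 mpk. The other codes held 1 group each, and no code held vehicle together with Helicon4. Helicon4neg library 2 stood apart from the other 28 in the slope of its log2 values on gene length (-0.321), with vehicle library 6 next (-0.186). Mean slopes were -0.04 for vehicle, -0.01 for Helicon4neg and 0.04 at either dose of Helicon4, and none of the 4 pairs of groups tested passed (smallest exact p = 0.0445, adjusted p = 0.288 over 8 tests added after the data were seen, 4 of them of the ribosomal protein share). The 2 pairs of 100 mpk with 30 mpk and with Helicon4neg were not tested for it. The slope nonetheless tracked the first principal component, which held 41% of the variance. Over the 29 libraries Pearson r was -0.939 and Spearman rho -0.872 (permutation p = 0.0001 each, adjusted p = 0.0002 over 4 relations, added after the data were seen). Without Helicon4neg library 2 and vehicle library 6 they were -0.876 and -0.841. Within vehicle alone r was -0.971 (n = 10, permutation p = 0.0001, adjusted p = 0.0002). Across genes, which are not independent replicates, fold changes and gene length had Spearman values of 0.24 for Helicon4 at 100 mpk, 0.35 at 30 mpk and 0.23 for Helicon4neg, each against vehicle. The values were 0.16 for Helicon4 against Helicon4neg at 30 mpk, -0.0012 between the doses and 0.1 for 100 mpk against Helicon4neg. Depth, mitochondrial share and share of the top 50 genes gave exact p values of 0.0859 or more in each of the 4 pairs of groups tested. The mean of the 5 endothelial markers was lower with Helicon4, at 2.77 ± 0.14 (SD, n = 10) on the log2 scale in vehicle and 2.16 ± 0.12 (SD, n = 5) at 100 mpk. The difference was -0.61 (exact permutation test, two-sided, p = 0.000666, adjusted p = 0.012 over 24 tests). At 30 mpk the difference from vehicle was -0.32 (exact p = 0.000999, adjusted p = 0.012) and from Helicon4neg -0.31 (exact p = 0.00533, adjusted p = 0.0426). CLDN5 carried most of this (-1.86, -1.16 and -1.52 in the same order). The test of the list against other genes did not pass at 30 mpk against vehicle (adjusted p = 0.172) or Helicon4neg (0.338). At 100 mpk its call was lost with an estimated correlation (0.116) and with the title code as a block (0.814). The fibroblast and leukocyte lists did not pass this test in any of the 4 pairs.

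The comparison of Helicon4 at 100 mpk with vehicle asked what the higher dose did to the tumors' transcripts. DKK4, which encodes a secreted Wnt inhibitor, fell from 32.5 ± 13.7 CPM (SD, n = 10) in vehicle to 0.0533 ± 0.0381 CPM (SD, n = 5), a log2 fold change of -4.88 ± 0.23 (SE). NKD1, a feedback inhibitor of Wnt signaling, fell from 289 ± 39.1 to 75.6 ± 18.4 CPM (log2 fold change -1.94 ± 0.12), and AXIN2, another, from 483 ± 45.5 to 268 ± 41.5 CPM (-0.85 ± 0.09). SP5, a transcription factor induced by Wnt, fell by 2.36 ± 0.16, NOTUM, a secreted enzyme that inactivates Wnt ligands, by 1.70 ± 0.14 and DKK1 by 2.64 ± 0.18 on the log2 scale. Transcripts of MYC did not pass the test, at 5161 ± 749 CPM against 5244 ± 845 CPM in vehicle (log2 fold change -0.02, 95% limits -0.25 to 0.22, adjusted p = 0.929), nor did LEF1 (-0.02 ± 0.09, adjusted p = 0.891). DKK4 at 100 mpk rested on 13 reads over 5 libraries against 14725 in vehicle, which makes it 626-fold lower by summed reads (95% limits 366 to 1180). Such limits cover counting error only.

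Among other core Wnt genes, TCF7 fell by 0.53 (adjusted p = 0.00195), ASCL2 by 0.72 (0.00792), ZNRF3 by 0.47 (0.0112) and CCND1 by 0.57 (0.0207) on the log2 scale. RNF43 (-0.10, adjusted p = 0.469) and LGR5 (-0.33, adjusted p = 0.139) did not pass. The CCND1 call was lost with only the 2 groups (adjusted p = 0.0505) and without Helicon4_100mpk library 2 (0.116) or library 5 (0.0527). The largest rises among well-expressed genes were those of TAC3, which encodes the neurokinin B precursor, from 2.69 ± 0.507 to 41.7 ± 18.1 CPM (log2 fold change 3.43 ± 0.21), PADI2, a peptidylarginine deiminase (2.64 ± 0.14), TNMD, which encodes tenomodulin (2.60 ± 0.20), and BMF, which encodes a pro-apoptotic BH3-only protein (2.27 ± 0.11). HRC (2.11), TMSB4X (2.00), KNG1 (1.84) and TBX2 (1.77) also rose. DEFA5, an antimicrobial peptide of Paneth cells, fell from 86.9 ± 37.0 to 1.97 ± 1.30 CPM (log2 fold change -4.91 ± 0.26). ADRA2C (-3.13), SERPIND1 (-2.81), SEMA5B (-2.79), C9orf84 (-2.79) and POMC (-2.67) followed it among the falls. By summed reads ADRA2C was 29.3-fold lower (88 reads against 4668, 95% limits 23.7 to 36.6) and SEMA5B 21.1-fold (97 against 3708, limits 17.3 to 26.1).

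In all, 1913 genes rose and 2130 fell among 13373 tested (limma, adjusted p under 0.05), and 582 and 676 of them by at least 1.5-fold. Without the libraries that stood apart the counts were 2488 and 2788. The groups shared no title code, and with the code as a block 141 genes passed, with a standard error that was 3.17 times as large at the median. Of 24 called core or largest-change genes 12 passed with the block: NKD1, DKK4, DKK1, TAC3, PADI2, BMF, HRC, TBX2, DEFA5, SERPIND1, SEMA5B and C9orf84. The other 12 were lost, and each is given here and below with its log2 fold change and adjusted p under the block: AXIN2 (-0.77, 0.422), SP5 (-2.05, 0.0612), NOTUM (-0.99, 0.227), TCF7 (-1.1, 0.325), ZNRF3 (-0.83, 0.657), CCND1 (-1.06, 0.694), TNMD (1.65, 0.402), TMSB4X (2.08, 0.147), KNG1 (1.94, 0.273), ADRA2C (-1.76, 0.193), POMC (-1.52, 0.631) and ASCL2 (0.22, 0.915), whose sign turned. Of 44 named calls that the block ended, 16 had a fold at least as large with it, 9 a smaller one within 1.5 times, 15 one smaller by more, and 4 turned. The replicate block lost ZNRF3 (0.0544) and CCND1 (0.066). Of all the calls 74.3% of the 4043 kept their sign with the title code block.

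**Figure D1:**
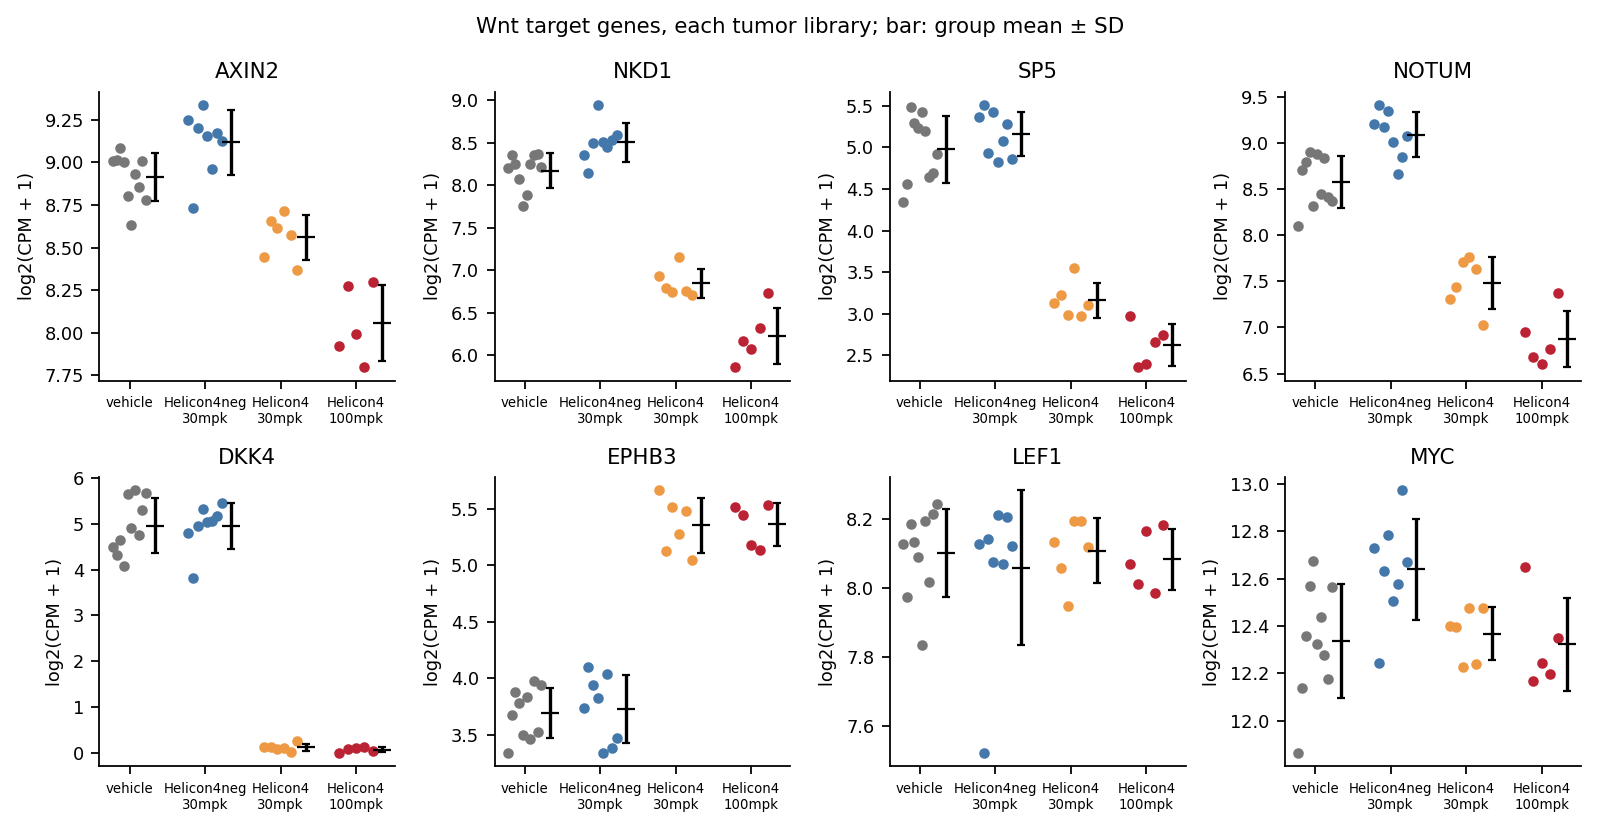
Expression of 8 genes of the Wnt target list as log2(CPM + 1), with 1 point per tumor library and bars for the group mean and SD (n = 10, 8, 6 and 5 from left to right). AXIN2, NKD1, SP5, NOTUM and DKK4 were lower with Helicon4 at both doses than with vehicle, EPHB3 was higher, and LEF1 and MYC did not pass the test.

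The gene lists were fixed before the data were examined, and 20 of 21 could be tested. Of the 24 measured Wnt target genes, 16 fell and 2 rose at 100 mpk against vehicle (16 and 2 adjusted over the list alone), with a median log2 fold change of -0.50 (camera, adjusted p = 4.38e-09; adjusted p = 0.116 with an estimated correlation). EPHB3, an ephrin receptor that the list holds as a target, rose from 12 ± 1.99 to 40.5 ± 5.32 CPM (1.67 ± 0.13). Of 12 intestinal stem cell markers 8 fell and 2 rose (8 and 2 adjusted over the list alone), led by TNFRSF19 (-1.96) and RGMB (-0.86), with a median of -0.45 (adjusted p = 0.0148; adjusted p = 0.116 with an estimated correlation). Among 27 genes of ribosome biogenesis and other classic MYC targets, 20 fell and 0 rose (23 fell adjusted over the list alone), with a median of -0.44 (adjusted p = 6.62e-08; adjusted p = 0.116 with an estimated correlation). TERT, which encodes the catalytic subunit of telomerase, fell by 0.86, MYBBP1A by 0.63, nucleolin (NCL) by 0.44 and GNL3 by 0.34 on the log2 scale. EPHB3 and TNFRSF19 passed with the title code as a block, and the calls of RGMB (-0.81, 0.437), TERT (-0.57, 0.77), MYBBP1A (-0.61, 0.732), NCL (-0.53, 0.612) and GNL3 (-0.44, 0.636) were lost.

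Of 22 S-phase genes 14 fell and 0 rose (16 fell adjusted over the list alone), with a median of -0.43 (adjusted p = 4.11e-07; adjusted p = 0.179 with an estimated correlation), among them the replication factors MCM3 (-0.63) and CDC45 (-0.74). Of 20 genes of the ATF4 and unfolded protein responses 11 fell and 0 rose (13 fell adjusted over the list alone), with a median of -0.40 (adjusted p = 2.04e-05; adjusted p = 0.116 with an estimated correlation). The amino acid transporter SLC7A5 fell by 0.90, the serine synthesis enzyme PHGDH by 0.76 and XBP1 by 0.54. Cholesterol synthesis genes also fell as a list, 7 of 19 passing downward and 0 upward (11 downward adjusted over the list alone), with FDPS at -0.60 and LSS at -0.77 and a median of -0.34 (adjusted p = 0.0012; adjusted p = 0.38 with an estimated correlation). Of the genes named here MCM3 passed with the title code as a block, and CDC45 (-0.69, 0.596), SLC7A5 (-1, 0.36), PHGDH (-0.49, 0.759), XBP1 (-0.46, 0.697), FDPS (-0.43, 0.696) and LSS (-0.10, 0.94) did not.

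Interferon-response genes rose: 15 of 20 measured members passed upward and 0 downward (16 upward adjusted over the list alone), with a median of 0.90 (adjusted p = 4.38e-09; adjusted p = 0.16 with an estimated correlation). IFI44L rose by 2.02 ± 0.24, IFIT3 by 1.51 ± 0.21, and OASL by 1.29 ± 0.19. IFIT1, which binds foreign RNA, rose from 9.50 ± 1.75 to 25.2 ± 9.13 CPM. A block by title code raised the median to 2.18 and kept IFI44L, IFIT1 and OASL, and the IFIT3 call was lost (2.25, 0.0867). Of 5 endothelial markers CLDN5 (-1.86) and EGFL7 (-0.61, adjusted p = 0.0415) fell, 3 adjusted over the list alone, with a median of -0.28 (adjusted p = 0.043; adjusted p = 0.116 with an estimated correlation). That list lost its call without Helicon4_100mpk library 2 (adjusted p = 0.0528), 4 (0.0539) or 5 (0.0612), with the host marker covariate (0.0805) and with the length slope covariate (0.0576). EGFL7 lost its call with the length slope covariate (0.0536) and without any of vehicle libraries 2 (0.0626), 3 (0.0599), 4 (0.0711), 6 (0.0711) and 8 (0.0697) or Helicon4_100mpk libraries 2 (0.119), 3 (0.136) and 5 (0.0507). Its sign turned with the title code as a block (0.72, adjusted p = 0.794), and CLDN5 shrank to -0.51 and lost its call (0.837). With the title code as a block the calls of the stem cell (adjusted p = 0.104), cholesterol (0.101) and endothelial lists (0.814) were lost.

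The other lists did not pass in this comparison. Of 23 Wnt pathway components 6 rose and 5 fell (8 and 6 adjusted over the list alone; list adjusted p = 0.679). CTNNB1, which encodes β-catenin, rose by 0.35 ± 0.06, while the scaffold genes DVL1 (-0.71) and AXIN1 (-0.44) fell. All 3 calls were lost with the title code as a block, at 0.21 (adjusted p = 0.809), -0.11 (0.937) and -0.24 (0.837). Members moved both ways in the lists of 8 co-amplified genes (2 up, 2 down, adjusted p = 0.862), of 8 enterocyte markers (2 up, 2 down, adjusted p = 0.828) and of 3 secretory markers (1 up, 1 down, adjusted p = 0.828). POU5F1B (-0.93), CDX2 (-0.59) and FABP2 (-1.64) fell, and KRT20 (0.73) and ATOH1 (0.52) rose. That block turned the sign of KRT20 (-0.58, adjusted p = 0.788) and ended the calls of POU5F1B (-0.37, 0.803), CDX2 (-0.38, 0.805), FABP2 (-1.84, 0.177) and ATOH1 (0.65, 0.67). So they did in the lists of 20 hypoxia and glycolysis genes (2 up, 2 down, adjusted p = 0.679) and of 16 p53 targets (4 up, 3 down, adjusted p = 0.828). NDRG1 (1.14), EGLN3 (0.74), SESN1 (0.75) and BTG2 (0.68) rose, and CDKN1A fell (-0.72). None of the 5 passed with the block, at 1.61 (0.24), 0.82 (0.554), 0.58 (0.678), 1.23 (0.0612) and -0.04 (0.976). Among 14 fibroblast markers 4 rose and 3 fell (adjusted p = 0.601). PDGFRA (1.13) and COL1A1 (0.77) rose, and BGN (-1.94) and MMP2 (-1.13) fell. Of 5 leukocyte markers 1 rose and 1, CTSS (-0.77), fell (adjusted p = 0.828). PDGFRA and BGN passed with the block, and COL1A1 (1.47, 0.135), MMP2 (-1.07, 0.163) and CTSS (-1.24, 0.263) did not. For these lists the counts adjusted over the list alone were the same except for p53 targets (4 up, 4 down) and secretory markers (1 up, 2 down).

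Lists with a single direction among called members, or none, were G2/M genes (0 up, 3 down, 2 down adjusted over the list alone, of 22, adjusted p = 0.23), neuroendocrine markers (0 up, 2 down, the same adjusted over the list alone, of 8, adjusted p = 0.679), where NCAM1 fell (-0.66, and -0.38 with the title code as a block, adjusted p = 0.785), immediate early genes (1 up, KLF6, 0 adjusted over the list alone, of 18, adjusted p = 0.828) and transcripts of the mitochondrial genome (0 of 13 by either adjustment, adjusted p = 0.862). KLF6 (0.45, adjusted p = 0.0184) lost its call without Helicon4_100mpk library 2 (0.0553), 3 (0.0618) or 4 (0.0508), and its sign turned with the title code as a block (-0.35, adjusted p = 0.827). The list of muscle, fat and skin markers had 1 measured member, KRT10 (-0.07, adjusted p = 0.692), and was not tested. The median, mean and test differed in sign for 3 of the lists that did not pass, those of co-amplified genes, enterocyte markers and p53 targets.

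**Figure D2:**
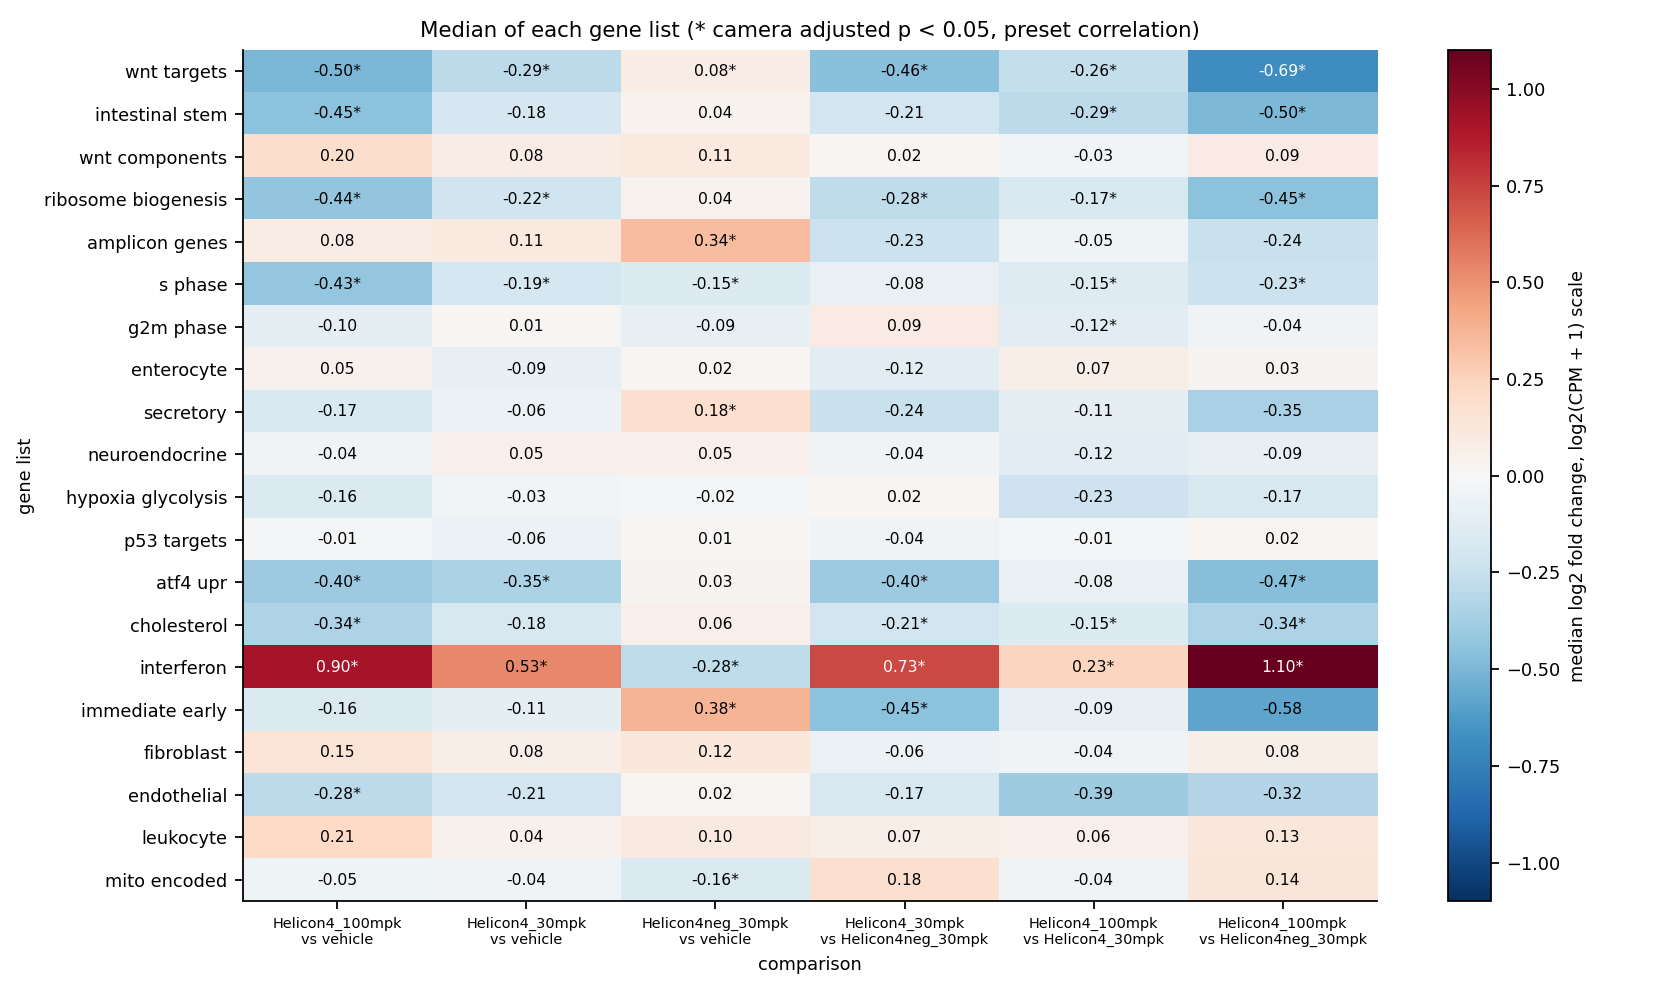
Median log2 fold change of each of the 20 tested gene lists (lines) in each of the 6 comparisons (columns), in color and as a number, with an asterisk where the camera test passed with its preset correlation. The interferon list had its highest median, 1.1, for Helicon4 at 100 mpk against Helicon4neg, and the Wnt target list was below 0 in all 5 comparisons that include Helicon4.

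Against vehicle, the lower dose of Helicon4 addressed the same question at 30 mpk. DKK4 fell from 32.5 ± 13.7 (SD, n = 10) to 0.0937 ± 0.0590 CPM (SD, n = 6), a log2 fold change of -4.83 ± 0.22 (SE), which is 355-fold by summed reads (27 against 14725, 95% limits 244 to 538). SP5 fell by 1.82 ± 0.15, NKD1 by 1.32 ± 0.12, NOTUM by 1.09 ± 0.14 and AXIN2 by 0.35 ± 0.09 on the log2 scale. MYC did not pass, with 5300 ± 402 CPM and a log2 fold change of 0.03 (adjusted p = 0.882). Nor did ASCL2 (-0.47, adjusted p = 0.118), LGR5 (-0.21, 0.401), ZNRF3 (-0.19, 0.365), TCF7 (-0.19, 0.326), CCND1 (-0.29, 0.291), RNF43 (0.16, 0.307) or LEF1 (0.01, 0.974). DEFA5 (-3.74), DKK1 (-2.46), POMC (-2.43), ADRA2C (-2.06), RASL11B (-2.05), SERPIND1 (-2.01) and SEMA5B (-1.97) were the other large falls. PADI2 rose by 2.23 ± 0.13, BMF by 1.84 ± 0.10, EPHB3 by 1.66 ± 0.12 and TAC3 by 1.65 ± 0.20, followed by CEL (1.60), TNMD (1.52), HRC (1.45) and KNG1 (1.37).

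In total 783 genes rose and 698 fell at 30 mpk against vehicle (limma, adjusted p under 0.05), of which 238 and 241 changed by at least 1.5-fold. Without the libraries that stood apart the counts were 1060 and 1138, and without Helicon4_30mpk library 1 the total fell from 1481 to 986. A block by title code left 74 genes, and 98.0% of the 1481 genes kept their sign. Of 20 called core or largest-change genes 11 passed with it, NKD1 (adjusted p = 0.036), DKK4 and DKK1 among them. With a standard error 2.64 times as large at the median, those lost were AXIN2 (-0.40, 0.987), SP5 (-1.54, 0.129), NOTUM (-0.71, 0.514), TAC3 (1.98, 0.129), TNMD (0.95, 0.987), KNG1 (1.29, 0.761), POMC (-1.58, 0.695), ADRA2C (-1.1, 0.721) and SEMA5B (-1.97, 0.111). Of 24 named calls ended 13 had a fold at least as large, 4 a smaller one within 1.5 times and 7 one smaller by more.

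Of the 24 Wnt targets 9 fell and 2 rose at 30 mpk (11 and 2 adjusted over the list alone), with a median of -0.29 (camera, adjusted p = 3.66e-07; adjusted p = 0.211 with an estimated correlation). Interferon-response genes rose, 11 of 20 upward and 0 downward (13 upward adjusted over the list alone), with a median of 0.53 (adjusted p = 2.14e-08; adjusted p = 0.211 with an estimated correlation) and with IFI44L at 1.24, OASL at 0.93 and IFIT3 at 0.88. Genes of the ATF4 and unfolded protein responses fell, 11 of 20 downward and 0 upward (13 and 1 adjusted over the list alone), with a median of -0.35 (adjusted p = 8.02e-07; adjusted p = 0.202 with an estimated correlation). The cystine transporter SLC7A11 fell by 0.79 and ASNS by 0.67. Ribosome biogenesis genes fell, 6 of 27 downward and 0 upward (9 downward adjusted over the list alone), with a median of -0.22 (adjusted p = 6.94e-06; adjusted p = 0.211 with an estimated correlation), among them ODC1 (-0.45), NCL (-0.31) and GNL3 (-0.27). The call of this list was lost with the title code as a block (adjusted p = 0.087). S-phase genes fell, 5 of 22 downward and 0 upward (8 downward adjusted over the list alone), with a median of -0.19 (adjusted p = 0.00018; adjusted p = 0.431 with an estimated correlation) and MCM3 at -0.34. Of these members OASL passed with that block. IFI44L (2.13, 0.115), IFIT3 (1.37, 0.463), SLC7A11 (-1.36, 0.111), ASNS (-0.88, 0.617), MCM3 (-0.45, 0.713) and ODC1 (-0.24), NCL (-0.28) and GNL3 (-0.27, 0.987 each) did not, and the interferon median was 1.32. That median rests on Helicon4_30mpk library 1, which had the highest interferon mean of its group (4.184).

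The remaining 15 tested lists did not pass at 30 mpk, among them those of stem cell markers (2 up, 3 down of 12, adjusted p = 0.85) and cholesterol synthesis (0 up, 1 down of 19, adjusted p = 0.0575). Single members that moved were SOX9 (1.20), TNFRSF19 (-0.99), the fibroblast marker FN1 (1.32), the p53 target BTG2 (0.95), CTNNB1 (0.24), FABP2 (-1.49) and CLDN5 (-1.16). Among them BTG2 passed with the title code as a block, and SOX9 (1.24, 0.0735), TNFRSF19 (-1.45, 0.142), FABP2 (-1.53, 0.208) and FN1 (0.83), CTNNB1 (0.19) and CLDN5 (-0.23, 0.987 each) did not. FLT1 (-0.27, adjusted p = 0.0497) lost its call with that block (-0.30, 0.987), with the replicate block (0.147) and without any 1 of vehicle libraries 2 (0.0564), 3 (0.0804), 5 (0.0526), 6 (0.0627), 7 (0.0853), 9 (0.0598) and 10 (0.0802) or of Helicon4_30mpk libraries 2 (0.0919), 3 (0.105), 4 (0.0647), 5 (0.144) and 6 (0.0503). Median, mean and test differed in sign for 5 lists that did not pass, those of stem cell, secretory, neuroendocrine and leukocyte markers and of hypoxia and glycolysis.

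Helicon4 and Helicon4neg were compared at the matched dose of 30 mpk, which sets the helicon against a compound whose name marks it as negative. DKK4 was at 0.0937 ± 0.0590 CPM (SD, n = 6) with Helicon4 and 31.3 ± 9.00 CPM (SD, n = 8) with Helicon4neg (log2 fold change -4.82 ± 0.23, SE; 342-fold by summed reads, 95% limits 235 to 519). The log2 difference was -2 ± 0.16 for SP5, -1.66 ± 0.12 for NKD1, -1.61 ± 0.14 for NOTUM and -0.55 ± 0.09 for AXIN2, and ZNRF3 was lower by -0.52 (adjusted p = 0.00968). No difference passed for MYC (-0.27, unadjusted 95% limits -0.50 to -0.04, adjusted p = 0.116), LEF1 (0.05, limits -0.13 to 0.22), RNF43 (-0.05, limits -0.25 to 0.16), TCF7 (-0.15, limits -0.40 to 0.11), LGR5 (-0.23, limits -0.57 to 0.11) or CCND1 (-0.23, limits -0.61 to 0.14). Without Helicon4neg library 2 the MYC difference passed (adjusted p = 0.0316). PADI2 (2.01), BMF (1.93), KNG1 (1.64), EPHB3 (1.62), CEL (1.55), TAC3 (1.5), TNMD (1.47) and NXPH4 (1.35) were higher with Helicon4. DEFA5 (-3.66), POMC (-2.93), ADRA2C (-2.53), DKK1 (-2.47), SEMA5B (-2.27), CEBPD (-2.16) and SERPIND1 (-2.10) were lower.

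Between these matched doses 1041 genes were higher and 977 lower with Helicon4 (limma, adjusted p under 0.05), 252 and 325 of them by at least 1.5-fold, and 1284 and 1295 without the libraries that stood apart. Code SH7081 held both groups: NKD1 was at 121 CPM in its single Helicon4 library against 367 ± 17.1 CPM (SD, n = 3) with Helicon4neg, and DKK4 at 0.10 against 36.7 CPM. A block by title code left 184 genes, and 100% of the 2018 genes kept their sign. The standard error was 2.05 times as large at the median. Of 22 called core or largest-change genes 16 passed with it, and AXIN2 (-0.64, 0.164), ZNRF3 (-0.46, 0.845), ASCL2 (-0.42, 0.993), KNG1 (1.67, 0.0504), TAC3 (1.56, 0.0752) and TNMD (1.03, 0.447) were lost. Of 22 named calls ended 11 had a fold at least as large, 9 a smaller one within 1.5 times and 2 one smaller by more.

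At the matched dose 12 of 24 Wnt targets were lower and 2 higher with Helicon4 (14 and 2 adjusted over the list alone), with a median of -0.46 (camera, adjusted p = 2.37e-09; adjusted p = 0.106 with an estimated correlation). The ASCL2 call (-0.59, adjusted p = 0.0473) was lost with only the 2 groups (0.107), with at least 5 CPM (0.0541) and without any 1 of Helicon4neg libraries 1 (0.0804), 2 (0.0592), 3 (0.0581), 4 (0.0521), 5 (0.0529) and 7 (0.0508) or of Helicon4_30mpk libraries 1 (0.109), 2 (0.0655), 3 (0.0545), 4 (0.058), 5 (0.0687) and 6 (0.108). Interferon-response genes were higher, 16 of 20 upward and 0 downward (19 upward adjusted over the list alone), with a median of 0.73 (adjusted p = 1.76e-13; adjusted p = 0.106 with an estimated correlation), including IFI44L (1.45), IFIT3 (1.25), IFIT1 (1.12) and OASL (1.07). Of 20 genes of the ATF4 and unfolded protein responses 12 were lower and 0 higher (13 and 1 adjusted over the list alone), with the chaperone HSPA5 at -0.68, ATF3 at -0.92 and a median of -0.40 (adjusted p = 1.04e-06; adjusted p = 0.106 with an estimated correlation). Ribosome biogenesis genes were lower, 10 of 27 downward and 0 upward (16 downward adjusted over the list alone), with a median of -0.28 (adjusted p = 6.76e-07; adjusted p = 0.151 with an estimated correlation), including NOLC1 (-0.40) and GNL3 (-0.34). The title code block kept the calls of the 4 interferon genes, HSPA5 and ATF3, with an interferon median of 1.49, and ended those of NOLC1 (-0.46, 0.405) and GNL3 (-0.44, 0.223).

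Immediate early genes, which respond within minutes to growth factors and stress, were lower with Helicon4 than with Helicon4neg: 5 of 18 passed downward and 0 upward (5 downward adjusted over the list alone), with a median of -0.45 (adjusted p = 0.00729; adjusted p = 0.485 with an estimated correlation). FOS differed by -1.73 ± 0.40, JUN by -1.33 ± 0.29 and DUSP1 by -0.70 ± 0.16, and the title code block ended these calls, at larger folds of -2.49 (0.212), -1.90 (0.212) and -1.14 (0.0991). Cholesterol synthesis genes passed as a list with 1 called member, DHCR7 (-0.41; 1 adjusted over the list alone), and a median of -0.21 (adjusted p = 0.0334; adjusted p = 0.633 with an estimated correlation). DHCR7 did not pass with that block (-0.29, 0.974). The list call was lost without Helicon4neg library 4 (0.105) or 8 (0.0588), without Helicon4_30mpk library 2 (0.0814) or 5 (0.145), with the host marker covariate (0.292) and with the title code as a block (0.345). The other 14 lists did not pass, but members of them did. CDX2 (-0.63), PVT1 (-0.45), KLF4 (-1.19), FABP2 (-1.55), CA2 (-0.56), BGN (-1.35), CLDN5 (-1.52) and CDKN1A (-0.82) were lower. ATOH1 (0.59), BTG2 (0.97), COL1A1 (0.97), SOX9 (1.08), CTNNB1 (0.31) and the endothelial marker ENG (0.52) were higher. FLT1 (-0.29, adjusted p = 0.0339) was lower, a call lost with the title code (-0.11, 0.999) and replicate (0.0692) blocks, with the host marker covariate (0.105) and without Helicon4neg library 4 (0.0663), 5 (0.0739) or 7 (0.0582) or Helicon4_30mpk library 2 (0.0642), 3 (0.0727) or 5 (0.106). CA2, BGN, BTG2, COL1A1 and SOX9 passed with the title code as a block. Calls lost with it were those of CDX2 (-0.62, 0.358), PVT1 (-0.17, 0.999), KLF4 (-1.32, 0.0752), FABP2 (-1.36, 0.0694), CLDN5 (-1.13, 0.394), CDKN1A (-0.66, 0.316), ATOH1 (0.81, 0.1), CTNNB1 (0.35, 0.377) and ENG (0.42, 0.838). For the fibroblast and leukocyte lists, which did not pass, median, mean and test differed in sign.

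Helicon4neg was also compared with vehicle, and its relation to Helicon4 is taken from the names only. TH, which encodes tyrosine hydroxylase of catecholamine synthesis, rose from 5.40 ± 2.45 CPM (SD, n = 10) to 25.8 ± 11.5 CPM (SD, n = 8), a log2 fold change of 2.04 ± 0.28 (SE). The immediate early transcription factors FOS (1.60 ± 0.35) and FOSB (1.03 ± 0.18) rose, as did ID3 (1.03 ± 0.17), an inhibitor of basic helix-loop-helix factors, and TNFRSF13C (1.04 ± 0.21). POTEF (1.19), POTEE (1.13) and POTEI (0.98) rose too, but they are near-identical paralogs whose reads are hard to assign. MAMDC4 (-0.76), SERPINI1 (-0.73), INHBE (-0.70; adjusted p = 0.0655 with only the 2 groups), DSPP (-0.68), PIR (-0.64), ZNF239 (-0.62) and STYXL1 (-0.59) fell. SAMD9 (-0.59, adjusted p = 0.034) fell too, a call lost with the replicate block (0.135) and without vehicle library 1 (0.0565), 5 (0.0564), 7 (0.052), 9 (0.0562) or 10 (0.0532) or Helicon4neg library 1 (0.0668), 4 (0.0837) or 7 (0.0584). Among the core Wnt genes NOTUM rose, from 387 ± 73.3 to 551 ± 92.0 CPM (0.52 ± 0.13, adjusted p = 0.0145), a call that was lost with the replicate block (0.0592) and, at a larger fold of 0.84, with the title code as a block (0.0506). Within code SH7080 NOTUM was at 329 to 340 CPM in 2 vehicle libraries and 514 to 680 CPM in 5 of Helicon4neg.

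NKD1 (0.33 ± 0.11, adjusted p = 0.0638), MYC (0.30 ± 0.10, adjusted p = 0.0782), AXIN2 (0.20 ± 0.08, adjusted p = 0.152) and SP5 (0.18 ± 0.14, adjusted p = 0.522) did not pass for Helicon4neg against vehicle. Nor did ZNRF3 (0.33, adjusted p = 0.12), RNF43 (0.21, 0.19), ASCL2 (0.12, 0.783), LGR5 (0.02, 0.966), TCF7 (-0.04, 0.895), LEF1 (-0.04, 0.818) or CCND1 (-0.06, 0.886). Without Helicon4neg library 2, NKD1 (adjusted p = 0.0116), MYC (0.0106), AXIN2 (0.0182), RNF43 (0.0246) and ZNRF3 (0.004) passed upward. In total 296 genes rose and 351 fell (limma, adjusted p under 0.05), 43 and 17 of them by at least 1.5-fold, and 996 and 1035 without the libraries that stood apart. The total of 647 became 2595 without Helicon4neg library 2 and 393 without library 4. Within code SH7080, TH was at 3.34 ± 0.210 CPM (SD, n = 2) in vehicle and 29.4 ± 12.7 CPM (SD, n = 5) with Helicon4neg, and FOS at 7.04 ± 3.31 against 16.9 ± 11.2 CPM. With the title code as a block 2 genes passed, TH (2.7) and ZNF610 (-0.97). The standard error was 1.69 times as large at the median, and the other 16 of 17 called core or largest-change genes were lost: NOTUM, FOS (0.89, 0.385), FOSB (0.97, 0.147) ID3 (1.20, 0.0954), TNFRSF13C (1.33, 0.116), POTEF (0.23, 0.735), POTEE (0.23, 0.688), POTEI (0.11, 0.858), MAMDC4 (-0.12, 0.815), SERPINI1 (-0.71, 0.144), INHBE (-1.24, 0.0954), DSPP (-0.74, 0.195), PIR (-0.33, 0.371), ZNF239 (-0.70, 0.147), STYXL1 (-0.31, 0.373) and SAMD9 (-1.04, 0.0954). Of 27 named calls ended 11 had a fold at least as large, 4 a smaller one within 1.5 times and 12 one smaller by more. The replicate block left 220 genes that rose and 246 that fell. ZNF610 was chosen after its values were seen.

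Of 8 measured genes near MYC and CDX2, described as co-amplified in this line, 3 rose and 0 fell with Helicon4neg (5 up and 2 down adjusted over the list alone), with a median of 0.34 (camera, adjusted p = 0.00159; adjusted p = 0.102 with an estimated correlation). PVT1, a noncoding transcript beside MYC, rose by 0.68, CASC11 by 0.51 and CDX2 by 0.40. The CDX2 call was lost with the replicate block (adjusted p = 0.11), with only the 2 groups (0.0599) and without Helicon4neg library 4 (0.0615) or 7 (0.0615), and that of the list with the title code as a block (0.107). Of 18 immediate early genes 4 rose and 0 fell (5 up adjusted over the list alone), DUSP1 (0.60) and JUN (0.92) among them, with a median of 0.38 (adjusted p = 0.00141; adjusted p = 0.617 with an estimated correlation; adjusted p = 0.462 with the title code as a block). The JUN call (adjusted p = 0.029) was lost with the host marker covariate (0.0858), only the 2 groups (0.0958) and without any 1 of vehicle libraries 2 (0.0508), 5 (0.0557), 6 (0.0503) and 7 (0.0537) or Helicon4neg libraries 1 (0.0596), 3 (0.0559), 4 (0.0851), 6 (0.0525), 7 (0.0708) and 8 (0.071). Interferon-response genes were lower, 1 of 20 downward, IFIT1 (-0.47), and 0 upward (2 downward adjusted over the list alone), with a median of -0.28 (adjusted p = 0.00131; adjusted p = 0.617 with an estimated correlation). The IFIT1 call (adjusted p = 0.0483) was lost with the replicate block (0.0958), at least 5 CPM (0.0548), without the libraries that stood apart (0.0581), without any 1 of vehicle libraries 2 (0.0805), 3 (0.0572), 5 (0.0617), 6 (0.0861), 7 (0.0752), 8 (0.0634), 9 (0.063) and 10 (0.0619) and without any 1 of Helicon4neg libraries 1 (0.0641), 3 (0.0769), 4 (0.111), 6 (0.0582), 7 (0.0795) and 8 (0.0799). S-phase genes were lower, 1 of 22 downward, POLA1 (-0.43), and 0 upward (1 downward adjusted over the list alone), with a median of -0.15 (adjusted p = 0.00131; adjusted p = 0.617 with an estimated correlation; 0.322 with the title code as a block). None of the members named here passed with that block: PVT1 (0.40, 0.161), CASC11 (0.36, 0.173), CDX2 (0.52, 0.161), DUSP1 (0.44, 0.302; 0.0501 with only the 2 groups), JUN (0.46, 0.549), IFIT1 (-0.52, 0.237) and POLA1 (-0.60, 0.111).

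Wnt targets passed upward as a list with Helicon4neg, 1 of 24 upward and 0 downward (4 upward adjusted over the list alone), with a median of 0.08 (adjusted p = 0.0351; adjusted p = 0.617 with an estimated correlation). This call was lost without vehicle library 1 (0.058) or 2 (0.0681) or Helicon4neg library 3 (0.0732), 4 (0.0659), 7 (0.0511) or 8 (0.053), with the host marker (0.602) and length slope (0.169) covariates and with the title code as a block (0.874). Its median was 0.01 with the host marker covariate and turned to -0.10 with the block. The 3 secretory markers passed upward, with KLF4 at 0.75 (0.41 with the title code as a block, adjusted p = 0.364; 1 up; 2 adjusted over the list alone) and a median of 0.18 (adjusted p = 0.0493; adjusted p = 0.491 with an estimated correlation). That call was lost without vehicle library 2 (0.0702), 5 (0.0718) or 8 (0.0816), without Helicon4neg library 1 (0.0576), 3 (0.0782), 4 (0.0547), 5 (0.0511), 6 (0.0757) or 7 (0.0511), with the pseudocount of 0.1 (0.0644), the host marker (0.118) and length slope (0.165) covariates and only the 2 groups (0.0602), and with the title code as a block (0.861). Mitochondrial transcripts passed downward with 0 of 13 members called by either the test over all genes or that adjusted over the list alone, and a median of -0.16 (adjusted p = 0.0493; adjusted p = 0.617 with an estimated correlation). Their call was lost without vehicle library 1 (0.121), 8 (0.187) or 9 (0.0532), without Helicon4neg library 4 (0.392), 7 (0.0826) or 8 (0.0609), with the pseudocount of 0.1 (0.0608), the replicate block (0.0773) and the host marker (0.256) and length slope (0.119) covariates, and with the title code as a block (0.531). The other 13 lists did not pass, though HSPA5 (0.40), DDIT3 (0.76) and HERPUD1 (0.29) of the ATF4 and unfolded protein response list rose. Their calls were lost with the title code as a block, at 0.27 (0.285), 0.82 (0.222) and 0.07 (0.768), and that of HERPUD1 also with only the 2 groups (0.0728). Median, mean and test differed in sign for the enterocyte and endothelial lists.

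**Figure D3:**
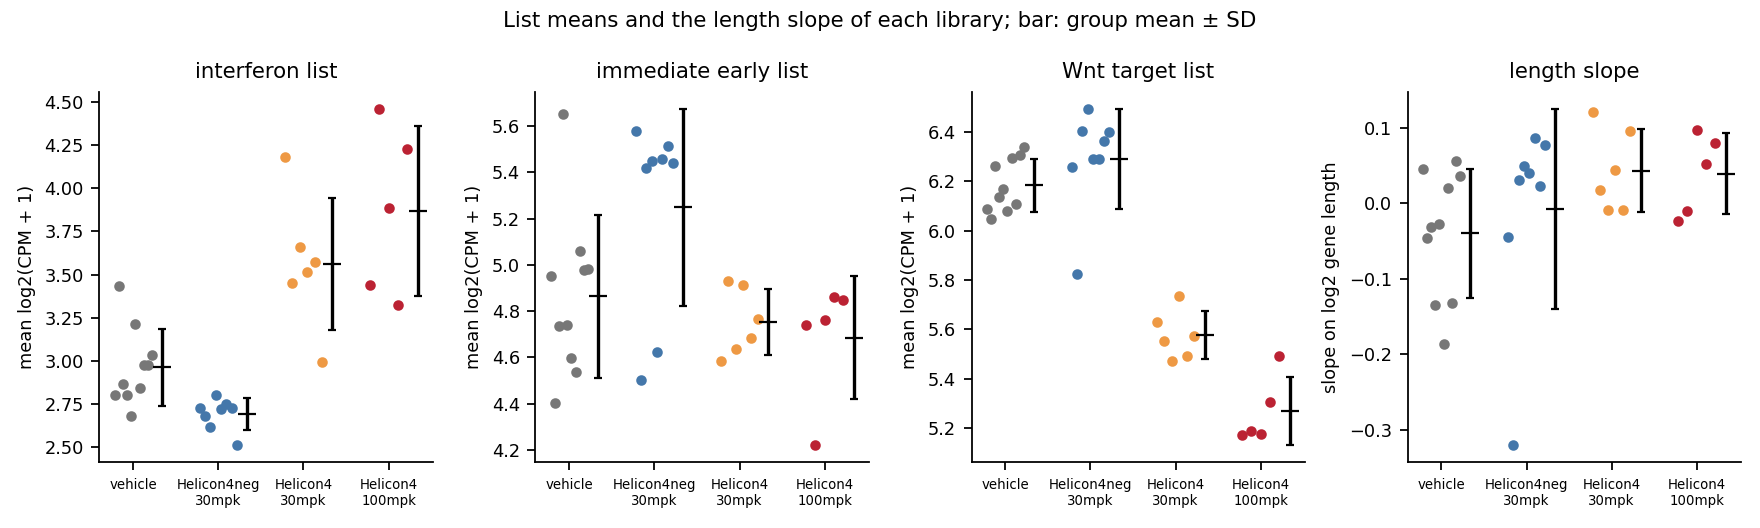
Mean log2(CPM + 1) of the interferon, immediate early and Wnt target lists and the slope of log2 values on log2 gene length, with 1 point per library and bars for the group mean and SD. Helicon4neg library 2 has the lowest length slope, -0.321, and vehicle library 4 the highest immediate early mean, 5.65.

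The higher dose of Helicon4 was compared with the lower. AXIN2 was at 268 ± 41.5 CPM (SD, n = 5) at 100 mpk and 378 ± 34 CPM (SD, n = 6) at 30 mpk (log2 fold change -0.50 ± 0.10, SE), and NKD1 was lower by -0.62 ± 0.14. WIF1, a secreted Wnt inhibitor, fell from 27.2 ± 4.3 to 9.03 ± 4.08 CPM (-1.56 ± 0.22), and HDC, which encodes histidine decarboxylase, by 1.45 ± 0.17. KCNJ6 (-1.76), MYH7B (-1.42), GC (-1.19) and ADRA2C (-1.07; 5.23-fold by summed reads, 95% limits 4.17 to 6.63) were also lower at 100 mpk. TAC3 (1.77 ± 0.23), SHISA3 (1.40), TMSB4X (1.39), TNMD (1.08), MACROD2 (0.85), HIST1H2AC (0.84) and TSPAN8 (0.81) were higher. C9orf84 (-1.15) was lower, as was DEFA5 (-1.17), a call lost with the replicate block (adjusted p = 0.0505) and without Helicon4_30mpk library 5 (0.0509) or Helicon4_100mpk library 2 (0.0758) or 3 (0.0776). TGFBI (1.33) was higher, which rested on Helicon4_100mpk library 4 in part (0.167 without it). That call was also lost with only the 2 groups (0.0538) and without Helicon4_30mpk library 1 (0.0688), 2 (0.0998), 3 (0.067), 4 (0.086) or 5 (0.0539) or Helicon4_100mpk library 3 (0.0706). TCF7 (-0.34, adjusted p = 0.187), RNF43 (-0.26, 0.218), ZNRF3 (-0.28, 0.361), CCND1 (-0.28, 0.533), ASCL2 (-0.25, 0.626), LGR5 (-0.12, 0.812), LEF1 (-0.02, 0.937), SP5 (-0.54 ± 0.18, adjusted p = 0.0987), MYC (-0.05 ± 0.13, adjusted p = 0.901) and IFIT1 (0.61 ± 0.18, adjusted p = 0.0532) did not pass. Without Helicon4_30mpk library 1 (0.0178) or Helicon4_100mpk library 1 (0.0174) or 4 (0.0166) IFIT1 did.

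Between the doses 233 genes were higher and 249 lower at 100 mpk (limma, adjusted p under 0.05), 74 and 101 of them by at least 1.5-fold, and 474 and 578 without the libraries that stood apart. The total of 482 became 209 without Helicon4_100mpk library 2, 252 without library 3, 253 without Helicon4_30mpk library 4 and 281 without library 2. Within code SH7083 the single library at 30 mpk had 27.9 CPM of WIF1 against 7.31 ± 1.55 CPM (SD, n = 4) at 100 mpk, and 8.65 CPM of TAC3 against 46.2 ± 17.5 CPM. Blocking by title code left 10 genes, WIF1, TAC3, KCNJ6 and GC among them, and the other 15 of 19 called core or largest-change genes were lost, with a standard error 1.77 times as large at the median. These were AXIN2 (-0.37, 0.985), NKD1 (-0.60, 0.778), NOTUM (-0.28, 0.985), HDC (-1.46, 0.0801), TMSB4X (1.49, 0.208), SHISA3 (0.77, 0.985), TGFBI (1.17, 0.985), TNMD (0.70, 0.985), ADRA2C (-0.67, 0.985), MACROD2 (0.62, 0.697), HIST1H2AC (1.12, 0.39), TSPAN8 (0.74, 0.507), MYH7B (-0.97, 0.574), DEFA5 (-1.48, 0.588) and C9orf84 (-1.56, 0.105). Of 26 named calls ended 10 had a fold at least as large, 10 a smaller one within 1.5 times and 6 one smaller by more.

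Stem cell markers were lower at 100 than at 30 mpk, 3 of 12 downward and 0 upward (6 downward adjusted over the list alone), with TNFRSF19 at -0.97 and RGMB at -0.52 and a median of -0.29 (camera, adjusted p = 1.08e-05; adjusted p = 0.00885 with an estimated correlation). This was the list call, of those in the 6 comparisons, that held with an estimated correlation. Wnt targets were lower, 5 of 24 downward and 0 upward (7 downward adjusted over the list alone), with a median of -0.26 (adjusted p = 7.38e-06; adjusted p = 0.368 with an estimated correlation). The NOTUM call (-0.61, adjusted p = 0.0283) was lost without any 1 of Helicon4_30mpk libraries 2 (0.0519), 3 (0.0652), 4 (0.086) and 5 (0.0605) or Helicon4_100mpk libraries 2 (0.109), 3 (0.106) and 4 (0.0692). S-phase genes were lower, 4 of 22 downward and 0 upward (7 downward adjusted over the list alone), with a median of -0.15 (adjusted p = 6.62e-05; adjusted p = 0.404 with an estimated correlation). Ribosome biogenesis genes were lower, with TERT (-0.77) and MYBBP1A (-0.53) the 2 called of 27 (2 adjusted over the list alone), and a median of -0.17 (adjusted p = 0.000528; adjusted p = 0.404 with an estimated correlation). Without Helicon4_100mpk library 2 the calls of MYBBP1A (0.0738) and of MCM2 (-0.52; 0.0506 without it) were lost. The title code block ended the calls of TNFRSF19 (-1.21, 0.208), RGMB (-0.63, 0.502), TERT (-0.72, 0.637), MYBBP1A (-0.47, 0.985) and MCM2 (-0.64, 0.395).

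Interferon-response genes were higher at 100 mpk as a list, with 0 of 20 called over all genes and 6 upward adjusted over the list alone, and a median of 0.23 (adjusted p = 0.000912; adjusted p = 0.508 with an estimated correlation). The call was lost without Helicon4_30mpk library 6 (0.0729). Cholesterol synthesis genes were lower, 3 of 19 downward and 0 upward (4 downward adjusted over the list alone), with a median of -0.15 (adjusted p = 0.00575; adjusted p = 0.508 with an estimated correlation). LSS (-0.57) lost its call without Helicon4_30mpk library 3 (0.0597), 4 (0.0774) or 5 (0.0514) or Helicon4_100mpk library 2 (0.128), 3 (0.0755) or 4 (0.0809). FDPS (-0.35) lost its own with the replicate block (0.0573) and without Helicon4_30mpk library 2 (0.0719), 3 (0.0573) or 4 (0.0658) or Helicon4_100mpk library 2 (0.114), 3 (0.072) or 4 (0.087). G2/M genes passed downward with 0 of 22 called by either adjustment, over all genes or adjusted over the list alone, and a median of -0.12 (adjusted p = 0.0294; adjusted p = 0.531 with an estimated correlation). Their call was lost without Helicon4_30mpk library 1 (0.0502) or 6 (0.126) or Helicon4_100mpk library 1 (0.523), with the host marker covariate (0.0581) and with the replicate block (0.0983). The other 13 lists did not pass. Of their members EGLN3 (0.58), PDGFRA (0.72), TIGAR (0.51) and KRT20 (0.80) were higher, the last lost without Helicon4_100mpk library 4 (0.0508). These calls and those of LSS and FDPS were lost with the title code as a block, at 0.49 (0.985), 0.78 (0.199), 0.49 (0.802), 0.37 (0.985), -0.37 (0.985) and -0.36 (0.895), and the interferon median was 0.83. That median rests on Helicon4_30mpk library 6, which had the lowest interferon mean of its group (2.995). Median, mean and test differed in sign for the p53 target and mitochondrial lists.

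Helicon4 at 100 mpk and Helicon4neg at 30 mpk differ in dose as well as compound, so their values stand side by side. NKD1 was at 75.6 ± 18.4 CPM (SD, n = 5) and 366 ± 59.98 CPM (SD, n = 8), a log2 difference of -2.27 ± 0.13 (SE), and NOTUM at 118 ± 27.5 and 551 ± 92.0 CPM (-2.22 ± 0.15). DKK4 (-4.87), SP5 (-2.54), AXIN2 (-1.06) and ZNRF3 (-0.80) were lower with Helicon4 at 100 mpk, as were KCNJ6 (-2.78), C9orf84 (-2.86), CDX2 (-0.99), FOS (-2.21) and BGN (-2.18). DEFA5 (-4.83), ADRA2C (-3.61), POMC (-3.17), SEMA5B (-3.10) and SERPIND1 (-2.90) were lower too. By summed reads ADRA2C was 40.5-fold lower (95% limits 32.8 to 50.5), SEMA5B 27.9-fold (22.8 to 34.4) and DKK4 604-fold (353 to 1130). TAC3 (3.27), TNMD (2.55), PADI2 (2.42), BMF (2.36), TMSB4X (2.23), KNG1 (2.11), HRC (1.88), HIST1H2AC (1.81) and IFIT1 (1.73) were higher. In total 2280 genes were higher and 2369 lower (limma, adjusted p under 0.05), 678 and 917 of them by at least 1.5-fold, 2721 and 2865 without the libraries that stood apart, and 189 in all with the title code as a block. Of 26 called core or largest-change genes 16 passed with that block, whose standard error was 2.7 times as large at the median, and AXIN2 (-1.01, 0.077), ZNRF3 (-0.82, 0.596), TNMD (1.73, 0.213), KNG1 (2.32, 0.0506) and POMC (-2.61, 0.0675) were among the 10 lost. IFIT1 and BGN passed with it too, and CDX2 (-0.90, 0.271) and FOS (-3.34, 0.223) did not.

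The other core Wnt genes in this comparison included calls that changed with the choice of fit. MYC was lower with Helicon4 at 100 mpk, at 5161 ± 749 CPM (SD, n = 5) against 6439 ± 935 CPM (SD, n = 8) with Helicon4neg (log2 difference -0.32 ± 0.12, SE, adjusted p = 0.0414). That call was lost with the replicate block (0.116), the title code block (-0.50, 0.834), the host marker covariate (0.178) and only the 2 groups (0.08). It was also lost without Helicon4neg library 1 (0.0647), 3 (0.0543), 4 (0.0689), 7 (0.0856) or 8 (0.0554) or Helicon4_100mpk library 2 (0.111), 3 (0.093), 4 (0.0983) or 5 (0.0603). CCND1 (-0.51, adjusted p = 0.042) was lost with the replicate block (0.0592), the title code block (-0.63, 0.949), the host marker covariate (0.193) and the quasi-likelihood test (0.0652). It was also lost without Helicon4neg library 1 (0.0567), 3 (0.0676), 4 (0.0542), 5 (0.0512), 6 (0.0641), 7 (0.066) or 8 (0.05) or Helicon4_100mpk library 2 (0.19), 3 (0.0684), 4 (0.0556) or 5 (0.0897). RNF43 (-0.31, adjusted p = 0.0248) was lost with the title code block (-0.36, 0.92), the host marker covariate (0.313), only the 2 groups (0.105) and without Helicon4neg library 4 (0.057) or Helicon4_100mpk library 2 (0.104), 3 (0.0563) or 4 (0.0911). TCF7 (-0.49, adjusted p = 0.00445) was lost with the title code block (-0.88, 0.404) and the host marker covariate (0.12), and ASCL2 (-0.84, adjusted p = 0.00285) with the title code block (-0.45, 0.999). LGR5 (-0.35, adjusted p = 0.125) and LEF1 (0.02, adjusted p = 0.86) did not pass. Of 16 named calls that the title code block ended here 10 had a fold at least as large, 5 a smaller one within 1.5 times and 1 one smaller by more.

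Of the lists in this comparison, Wnt targets were lower, 18 of 24 downward and 2 upward (18 and 2 adjusted over the list alone), with a median of -0.69 (camera, adjusted p = 7.87e-10; adjusted p = 0.108 with an estimated correlation). Stem cell markers were lower, 8 of 12 downward and 2 upward (8 and 2 adjusted over the list alone; median -0.50, adjusted p = 0.0099; adjusted p = 0.108 with an estimated correlation; 0.0711 with the host marker covariate and 0.056 with the title code as a block). Ribosome biogenesis genes were lower, 20 of 27 downward and 0 upward (21 downward adjusted over the list alone; MYBBP1A -1.02; median -0.45, adjusted p = 8.18e-08; adjusted p = 0.108 with an estimated correlation). S-phase genes were lower, 9 of 22 downward and 0 upward (9 adjusted over the list alone; MCM3 -0.52; median -0.23, adjusted p = 0.00456; adjusted p = 0.569 with an estimated correlation). Genes of the ATF4 and unfolded protein responses were lower, 13 of 20 downward and 2 upward (16 and 2 adjusted over the list alone; HSPA5 -0.70; median -0.47, adjusted p = 3.98e-05; adjusted p = 0.108 with an estimated correlation). Cholesterol synthesis genes were lower, 9 of 19 downward and 0 upward (11 downward adjusted over the list alone; DHCR7 -0.78; median -0.34, adjusted p = 0.0014; adjusted p = 0.378 with an estimated correlation; 0.0515 with the host marker covariate). Interferon-response genes were higher, 19 of 20 upward and 0 downward (19 adjusted over the list alone; median 1.1, adjusted p = 2.67e-11; adjusted p = 0.108 with an estimated correlation). The title code block raised the interferon median to 2.34 and ended the calls of MYBBP1A (-1.07, 0.158), MCM3 (-0.77, 0.056), HSPA5 (-0.81, 0.174) and DHCR7 (-0.73, 0.525). The other 13 lists did not pass, and for those of Wnt components and of enterocyte, fibroblast and leukocyte markers median, mean and test differed in sign.

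Responses to the 2 doses of Helicon4 were compared through the vehicle libraries they share. Of the genes called in both, 657 rose at both doses and 587 fell at both, where independent calls would give 112 and 111, and 1 moved in opposite directions. Across all genes, which are not independent replicates, the fold changes had a Pearson r of 0.844 and a covariance of 0.099. In 100 simulations of unchanged groups 0 genes were shared, which is no yardstick as none was changed. Covariance averaged 0.00785 and r ranged from -0.666 to 0.902, so r alone does not separate these. Helicon4 and Helicon4neg at 30 mpk shared 83 genes in the same direction and 51 in opposite directions (r 0.193, covariance 0.0102 against 0.00638 simulated). Helicon4 at 100 mpk and Helicon4neg shared 127 and 112 (r 0.045, covariance 0.00334 against 0.00825 simulated). With the vehicle libraries divided at random into 2 separate sets, 20 times, the median same-direction counts were 741, 22.5 and 40 and the median r values 0.755, 0.0188 and -0.0482 in the same order.

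**Figure D4:**
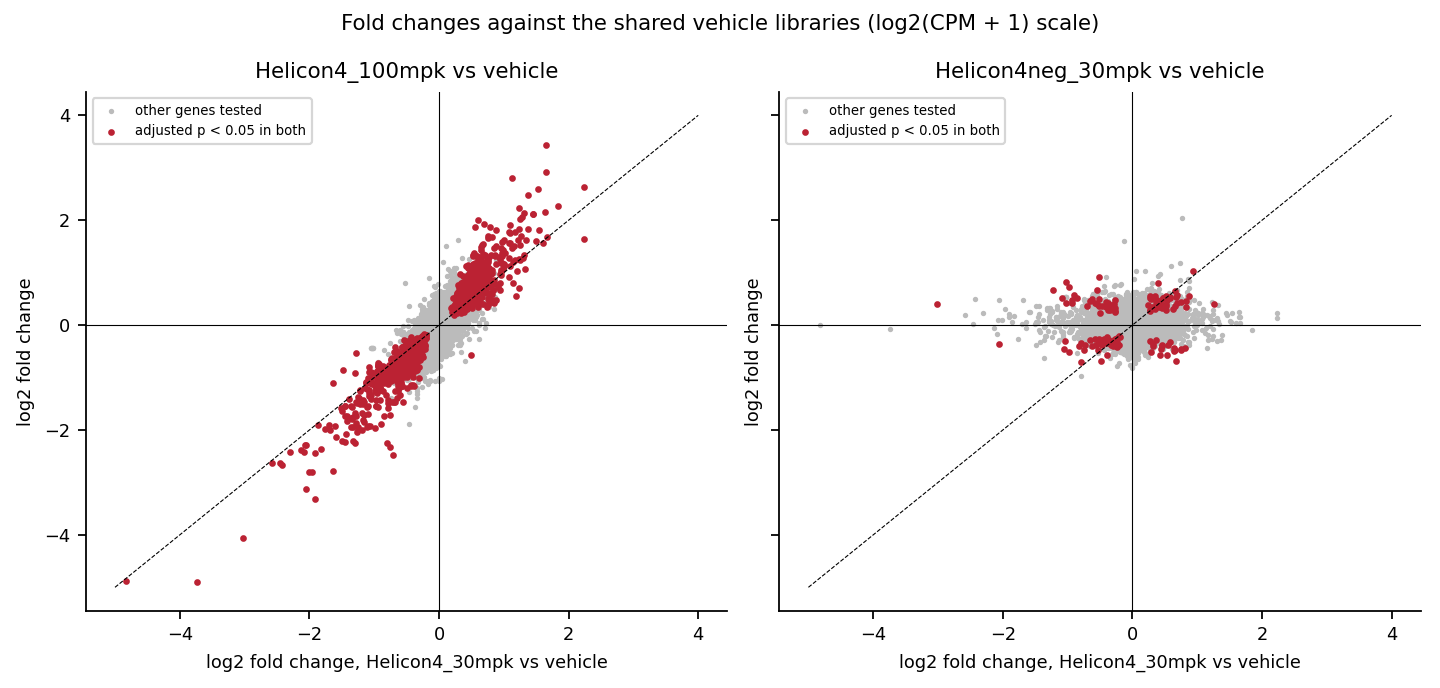
Log2 fold changes against vehicle of all 13373 tested genes for Helicon4 at 30 mpk (horizontal axes) against Helicon4 at 100 mpk (left) and Helicon4neg (right), with 1 point per gene, red where both passed, and a dashed line of equality. On the left 1244 genes passed in the same direction and 1 in opposite directions; on the right 83 and 51.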

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

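The tests of leukocyte markers, of library scaling, of the MYC transcript and of single libraries of code SH7080 below were chosen only after the result was seen, as was the length slope, and the tests by splits, by length slope covariate and by title code had their outcomes written down before they were run. A library is listed here where its gap to the nearest other library of its group was wide for the group's range (Dixon's criterion). Chance gives this in about 1 in 20 groups, and here it was met in 48 of 504 tests (9.52%), 28 of them in Helicon4neg library 2. Measures within that library are not independent.

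Helicon4neg library 2 lay far from the other 7 of its group in column sum (1.263 M), share of ribosomal protein transcripts (19.09%), length slope (-0.3207) and the means of the fibroblast (2.901), endothelial (3.25) and leukocyte (1.925) lists. It was high for ASNS (111.8 CPM, others 54.3 to 72.3), MCM2 (470.6), PIR (41.62), PHGDH (676.8), CDC45 (107.5), RASL11B (31.19), EGFL7 (101), ASCL2 (138.2), CLDN5 (44.66) and TMSB4X (72.52). It was low for DKK4 (13.05 CPM, others 26.7 to 43.1), CCND1 (9.025), FN1 (11.04), TNFRSF19 (34.98), MYBBP1A (135.6), LEF1 (182.8), KLF6 (30.86), LGR5 (0.374), HDC (313.6), WIF1 (22.12), SHISA3 (0.982) and ZNRF3 (63.12).

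Among vehicle libraries, 4 was high for the immediate early mean (5.652) and DUSP1 (15.06 CPM), 9 for ASNS (118.2) and INHBE (24.28), 10 for KNG1 (5.72) and 2 for OASL (1.768), and 6 was low for MYBBP1A (87.7). Helicon4neg library 6 was high for IFI44L (0.562 CPM). At 30 mpk of Helicon4, library 1 was high for NDRG1 (14.51 CPM), IFIT3 (9.072) and NCAM1 (1.542), and library 4 was low for the share of the top 50 genes (17.49%) and high for SERPIND1 (2.308). At 100 mpk, library 2 was low for the immediate early mean (4.22), library 5 was high for SEMA5B (0.852 CPM), NCL (1222) and GC (26.3), library 3 for FOSB (5.553) and library 4 for SHISA3 (32.06) and TGFBI (96.96; others 15.2 to 22.3).

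Among 100 splits of the libraries of each pair of groups, the real one included, only the real split gave as many genes for Helicon4 at 100 mpk against vehicle (4043 genes, highest other 2339), at 30 mpk against vehicle (1481, 217), against Helicon4neg at 30 mpk (2018, 1355), for 100 against 30 mpk (482, 287) and for 100 mpk against Helicon4neg (4649, 3784). This does not exclude chance, as libraries cannot be exchanged across codes. The splits do not test the code itself, and with it as a block 141, 74, 184, 10 and 189 genes were called in the same order. For Helicon4neg against vehicle 2 of 100 splits gave as many, the real one with 647 genes and another with 1682. This share is under 0.05 but does not decide on chance, as the other split points to a structure of the samples. That split put vehicle libraries 1, 9 and 10 with Helicon4neg libraries 1, 4, 5, 6 and 7. It left the 7 vehicle libraries of code SH7079 on the other side, so libraries cannot be taken as exchangeable across codes. With the block 2 genes were called there.

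The interferon list was higher with Helicon4 (median 0.90 at 100 mpk against vehicle). The tests argue against the length axis as the whole cause, since the median was 0.896 with the length slope as a covariate (adjusted p = 1.14e-08). Title code order cannot be told apart from the compound: with the code as a block the median was 2.18, and the codes tie Helicon4 to the other groups only through 1 Helicon4_30mpk library each in SH7081 and SH7083, beside 2 vehicle and 5 Helicon4neg libraries in SH7080. More host leukocytes cannot be told apart either, because the leukocyte list, whose median was 0.215, had 5 measured members and 0 of 8 abundant leukocyte transcripts in the table. A response of the tumor cells to Helicon4 may be the source but was not tested.

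The immediate early list was higher with Helicon4neg than with vehicle (median 0.378, mean 0.384). The length axis is argued against as the whole cause by a median of 0.317 with its covariate (adjusted p = 0.00823). Title code order cannot be told apart from the compound: within code SH7080 the mean difference was 0.135 ± 0.381 (SE; 2 and 5 libraries, one-sided exact p = 0.381, 21 splits), and with 1 of its Helicon4neg libraries left out it ran from 0.019 ± 0.38 (without library 1) to 0.288 ± 0.326 (without library 2). The value with all libraries is under 0.5 of the pooled 0.384, which by the bound first written would have counted for the code, but it is over that share without library 2 (0.288 of 0.491) or 5 (0.258 of 0.473), and that its error must also lie below the bound was required only after the value was seen. An effect of Helicon4neg and differences in handling of the tumors could each underlie the pattern and were not tested.

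The ribosome biogenesis list was lower with Helicon4 at 100 mpk than with vehicle (median -0.437) while MYC did not pass. Against Helicon4neg MYC passed (-0.3165, adjusted p = 0.0414), but not with the replicate block (0.116) or without any 1 of several libraries (above). Scaling of libraries cannot be told from the list median minus that of all genes, -0.442, because the deposited values were already centered between libraries, so the fall is one relative to other genes. The length axis as the whole cause is argued against by a median of -0.328 with its covariate (adjusted p = 7.82e-07). In the fit without codes the lower 95% limit of MYC against vehicle, -0.2533, lay above the list median. With the title code as a block MYC was -0.2942 ± 0.3783 (SE), so a fall as large as the list's cannot be excluded. MYC protein was not measured. No vehicle library shared a title code with Helicon4, so the code remains open. That Helicon4 may lower these transcripts, through the MYC transcript or by another route, is a hypothesis that was not tested.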

How the results depend on the processing

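Alternatives chosen after the data were seen are named above. Comparisons are given in the order Helicon4 at 100 mpk, at 30 mpk and Helicon4neg against vehicle, Helicon4 against Helicon4neg at 30 mpk, 100 against 30 mpk, and 100 mpk against Helicon4neg, with 4043, 1481, 647, 2018, 482 and 4649 genes as reported. A minimum of 1.5-fold left 1258, 479, 60, 577, 175 and 1595, by its construction. The title code as a block left 141, 74, 2, 184, 10 and 189, with standard errors 1.69 to 3.17 times as large at the median, since few libraries link the groups within codes.

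Library weights gave 6223, 3844, 3897, 4921 and 3904 genes in the first 5 comparisons. The host marker covariate gave 2815 at 30 mpk against vehicle and 3804 against Helicon4neg. The length slope covariate gave 2249 (30 mpk against vehicle), 2383 (Helicon4neg against vehicle), 3440 (Helicon4 against Helicon4neg at 30 mpk) and 2000 (between doses). Without the libraries that stood apart there were 2031 for Helicon4neg against vehicle and 1052 between doses, DESeq2 gave 1105 and 750 for the same pair of comparisons, and a fit of only the 2 groups gave 366 for Helicon4neg against vehicle. For these the cause was not tested. The other alternatives that left all libraries in stayed within 1.5 times of the reported counts.

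Leaving out 1 library gave 2964 to 4381, 986 to 1623, 393 to 2595, 1503 to 2299, 209 to 704 and 3716 to 5218 genes. Libraries that moved counts over 1.5 times are given above. Lists called, reported as 8, 5, 7, 6, 7 and 7, ranged over 7 to 8, 5 to 7, 4 to 9, 5 to 7, 5 to 8 and 7 to 9, the 4 without Helicon4neg library 4. With an estimated correlation they were 0, 0, 0, 0, 1 and 0, since camera then allows for members that move together. With the title code as a block 2 lists passed for Helicon4neg against vehicle; the cause was not tested.

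The replicate number as a block gave 4431, 1519, 1605, 366 and 4468 genes in the comparisons other than Helicon4neg against vehicle, where 220 rose and 246 fell (296 and 351 reported). It weakened 12 gene results.

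With the vehicle libraries divided into 2 sets, which leaves fewer samples, shared same-direction calls were 741 (1244 reported) for the 2 doses, 22.5 (83) for Helicon4 and Helicon4neg at 30 mpk and 40 (127) for 100 mpk and Helicon4neg, with r of 0.755, 0.0188 and -0.0482. At least 5 CPM left 48 and 70 shared calls for the last 2 pairs; the cause was not tested.

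Of 284 gene results, 4 reversed, all with the title code as a block at 100 mpk against vehicle: ASCL2 (0.2242, adjusted p = 0.915), KRT20 (-0.5797, 0.788), KLF6 (-0.3537, 0.827) and EGFL7 (0.7212, 0.794); the cause was not tested. That block kept direction and side of the threshold for 125 and weakened 155; of these 159 ended calls 71 had a fold at least as large and 41 a smaller one within 1.5 times. Leaving out 1 library kept 3992 of 4135 values and weakened 133. A fit of only the 2 groups weakened 10 and the host marker covariate 6. The pseudocount, no filter, TMM factors and plain limma kept 284 of 284; the TMM factors were near 1, so that alternative moved little. Of 40 called lists the title code block weakened 12, the host marker covariate 8, the length slope covariate 4, the pseudocount 2, the replicate block 2, only the 2 groups 1 and the estimated correlation 39. The block turned the median of 1 of them, Wnt targets with Helicon4neg (-0.0979). RLE size factors and a prior count, planned for counts, were not run because the values took the branch for CPM. Depth limits few genes: DKK4 with Helicon4 rests on 13 and 27 reads.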

Other observations

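The histone share and its tests were chosen after the data were seen. Transcripts with HIST symbols made up 0.0436 ± 0.00486% of values (SD, n = 5) with Helicon4 at 100 mpk and 0.0256 ± 0.00311% (SD, n = 10) in vehicle (exact permutation test, two-sided, p = 0.000666, adjusted p = 0.00333 over 5 tests). The share was 0.0334 ± 0.00369% (n = 6) at 30 mpk (adjusted p = 0.00375 against vehicle, 0.00555 against Helicon4neg and 0.0162 for 100 against 30 mpk) and 0.0269 ± 0.00191% (n = 8) with Helicon4neg (exact p = 0.321 against vehicle). Of 30 such genes 18 rose and 1 fell at 100 mpk against vehicle, with a median log2 fold change of 0.48, among them HIST1H2AC (1.49 ± 0.15) and HIST1H2BD (0.94 ± 0.09). No title code held vehicle with Helicon4, and no explanation was tested.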
